A study of Homo sapiens with 29 samples.

How the data were processed

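Total RNA of 29 cell lines of diffuse large B cell lymphoma, 9 ABC and 20 GCB by the labels, was measured by RNA sequencing with 1 library per line. Per the labels, cells were grown in Iscove's medium with fetal calf serum, except OCI-LY10, which was grown with human plasma. RNA was extracted with TRIzol from cells in log phase, and stranded libraries were made from total RNA after depletion of ribosomal RNA (Ribo-Zero Plus) and sequenced on an Illumina HiSeq as read pairs of 100 bp. The labels name CASAVA 1.8, STAR 2.7.2 and featureCounts (no version) with genome build GRCh37, but not their settings, so the strand setting and the filters of the counting are unknown. The authors deposited a table of raw counts per gene and a table of TPM (transcripts per 1000000), in which the authors' TPM values of each line sum to 1000000. Every value in the count table was a whole number, and both tables held 29 sample columns, each of which matched a sample. No batch was labelled, and no paired analysis was possible because each line was sequenced once and no label links lines of the ABC and GCB groups.

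The tables hold 48710 genes with GRCh37 coordinates and identifiers of GENCODE 29. Gene classes came from the GENCODE 29 annotation on GRCh38: 47317 genes matched by identifier and 448 by name, and 945 had no match. Of that annotation's 5583 antisense genes the tables hold 110, of its 1879 miRNA genes 1 and of its 58 ribosomal RNA genes 0, so these classes could not be assessed, and CD24 of the B cell identity list is absent too. Positions in the text are those of the deposited tables.

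Counts were analysed with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Genes were kept by filterByExpr with the groups, which left 21873 genes and at least 99.1% of each line's counts. After TMM scaling, a quasi-likelihood model with ABC or GCB as its only term was fitted with robust=TRUE (legacy=TRUE) and tested two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The median fold change of all genes was −0.03. Log2 CPM used a prior count of 2, so log2 CPM values of genes near the floor depend on this prior. The depth per line was 34341206 to 86578116 counts, and the floor was 3 counts of a line's total. Floors cover counting error only, since reads are not independent molecules. Counts were also simulated with the dispersion trend of these data, with 50 genes averaging at least 1 CPM changed at each size. On these the test recovered 14% of 2-fold, 58% of 4-fold, 86% of 8-fold and 100% of 16-fold changes, with 1 false call. The simulated genes were independent and had no spread of their own beyond the trend, so these rates need not hold for the real lines.

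Gene lists, tests and settings were fixed before the data were examined, unless the text says otherwise. The 27 lists were tested with camera on log2 CPM with a preset correlation of 0.01 between genes, two-sided and adjusted over the 24 lists that had at least 5 genes tested. With an estimated correlation 4 of the 11 called lists held: ABC subtype, GCB subtype, cytokine and JAK-STAT, and BCL2 family genes. With fry, which tests whether a list's genes move one way and makes no comparison with other genes, 9 lists were called. The lists cover subtype genes, signalling, differentiation, metabolism, antigen presentation and markers of other cell types. A list score is the mean over its genes of log2 CPM centred on the mean over lines, and the subtype score is that of ABC minus that of GCB subtype genes.

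Named genes followed a rule, with immunoglobulin and T cell receptor segments and Y-linked genes left out. They were the 8 protein-coding genes with the largest called changes in each direction and a mean of at least 5 CPM in the higher group; the 5 with the smallest adjusted p in each direction; BCL6, BCL2, CXCR4, MYC, IRF4, PRDM1, MME and FOXP1; per list up to 2 called genes in each direction or, with no call, the gene with the smallest p; 3 long noncoding genes in each direction; and genes lost in at least 3 lines. Other genes named were chosen after their values were seen.

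Single values were compared between groups by two-sided exact permutation tests over all 10015005 regroupings of 9 and 20 lines, with Benjamini-Hochberg adjustment over the composition measures. Loss of expression was set at under 1 in 20 of the median CPM of all lines, for genes with a median of at least 1 CPM, and compared by two-sided Fisher's exact tests; for 2 of the genes assessed the result is not reported here. Correlations were computed within groups or clusters with two-sided permutation p, exact for under 10 lines and from 100000 draws otherwise, adjusted over the family of 14. A family of 12 had been planned; relations whose lines fell into clusters, with a gap of at least 2.5 on the log2 scale and at least 3 lines on each side, were split or left untested after the data were seen. These calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

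Alternatives were DESeq2 size factors or library size for scaling; no filter, or at least 1 CPM in 9 lines; the DESeq2 1.42.0 Wald test, limma-voom, and limma on log2 TPM with 1 or 0.1 added; glmTreat against 1.5-fold; fitting without robust; the library number as a covariate; leaving out OCI-LY10 and each line in turn; 5000 variable genes; the subtype score on 15 genes; other fractions for loss; TPM in place of CPM; and 20-fold in place of 50-fold for line-restricted genes. Chosen after seeing the data were the log10 total count as a covariate, the newer dispersion estimate of edgeR (legacy=FALSE), leaving out HLY1, or HLY1, RCK8 and PFEIFFER, clusters in correlations, and counting genes at an equal depth.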

Results

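RNA sequencing of ribosome-depleted total RNA was compared between human cell lines of diffuse large B cell lymphoma, a tumour of mature B cells. The labels placed 9 lines in the activated B cell-like (ABC) group and 20 lines in the germinal centre B cell-like (GCB) group. The ABC lines were HBL1, OCI-LY10, RCK8, RIVA, U2932, HLY1, TMD8, SUDHL2 and LY3. The GCB lines were BJAB, DB, DOHH2, FARAGE, HT, KARPAS 422, OCI-LY18, OCI-LY1, WSU-DLCL2, OCI-LY7, OCI-LY8, SUDHL10, NU-DHL1, SUDHL4, SUDHL5, SUDHL6, SUDHL16, TOLEDO, RL and PFEIFFER. Each line had 1 library, so the lines were the replicates. Total counts per line ran from 34341206 in HBL1 to 86578116 in DOHH2, with a median of 66086056, and the means of 64.4 M in ABC lines and 59.6 M in GCB lines (M, 1000000 counts) did not differ (exact permutation adjusted p = 0.665). At these depths a gene with no count could have had up to 0.0347 to 0.0874 counts per 1000000 (CPM), depending on the line. Fold changes below are log2 values of ABC over GCB lines, fitted to the counts, with a standard error (SE) derived from the test. It is the size of the fold change divided by the square root of the F statistic, not a standard error of the fitted coefficient. Group levels are means of log2 CPM with the standard deviation (SD) over 9 and 20 lines. Differences of group levels need not equal the fitted fold changes.

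The ABC lines lay towards one end of the main axis of variation, while the GCB lines were spread over most of it. On the first principal component, which held 20.8% of the variance of the 1000 most variable genes, the ABC lines averaged 55.2 ± 22.1 and the GCB lines −24.9 ± 38.6 (SD; exact permutation p = 3.0e-06), and 2 GCB lines lay above the lowest ABC line (5 with log2 TPM plus 1 and 1 with 5000 variable genes). GCB lines ran from −69.6 (SUDHL10) to 41.1 (PFEIFFER) on the first component, with a gap between SUDHL6 (−26.2) and OCI-LY8 (10.1). Those above the gap reached into the ABC lines, which ran from 30.1 (U2932) to 91.1 (OCI-LY10). The widest gap on this axis thus lay within the GCB group. The second component, with 7.56% of the variance, did not separate the groups (exact permutation p = 0.179). The subtype score, the score of ABC minus that of GCB subtype genes, averaged 3.63 ± 1.66 in ABC lines and −1.63 ± 2.25 in GCB lines, a difference of 5.27 (exact permutation p = 4.6e-06). It ran from 0.79 in U2932 to 5.96 in HBL1 among ABC lines and from −4.42 in KARPAS 422 to 2.46 in DOHH2 among GCB lines, so that 7 of 9 ABC lines lay above every GCB line and 16 of 20 GCB lines below every ABC line. The subtype genes are of the kind on which such labels rest, and so are not independent evidence of the grouping. By correlation over the genes tested, 3 lines lay closest to a line of the other group: the ABC lines RCK8 (to FARAGE, r = 0.864) and HLY1 (to TOLEDO, r = 0.857), and the GCB line PFEIFFER (to U2932, r = 0.882). These correlations were across genes, which are not independent replicates.

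**Figure D1:**
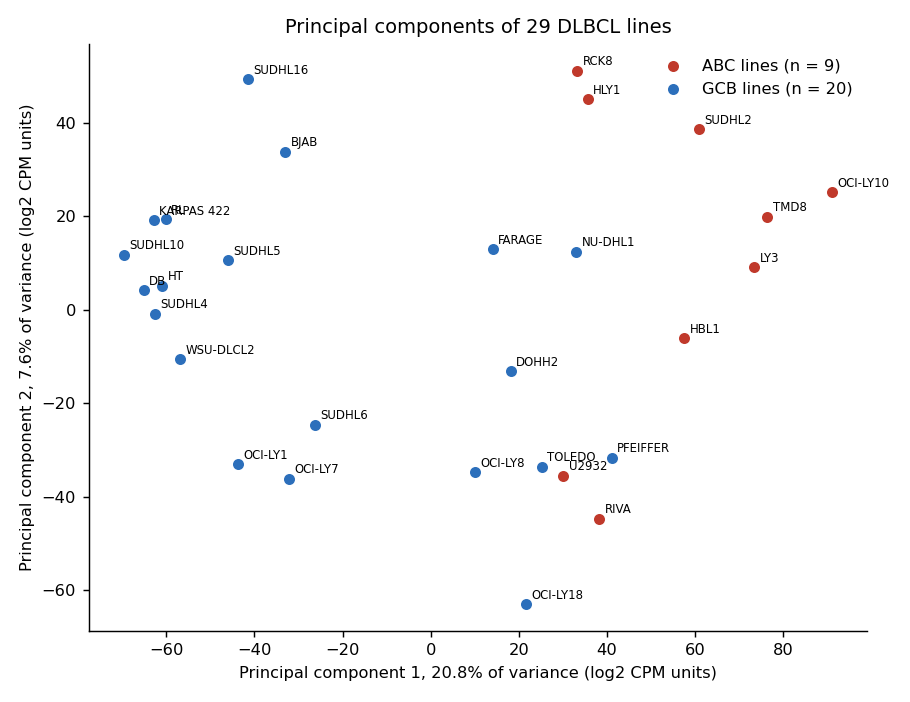
The first principal component (20.8% of the variance) is plotted against the second (7.56%), with 1 point per cell line, for 9 ABC and 20 GCB lines. The ABC lines lie towards higher values of the first component, and 2 GCB lines lie above the lowest ABC line.

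The comparison asked which genes differ in level between ABC and GCB lines. Of 21873 genes tested, 929 passed an adjusted p of 0.05, 650 higher and 279 lower in ABC lines, and 748 of them changed at least 2-fold (559 higher, 189 lower). The strongest call was ZNF385C, a zinc finger gene, at 4.04 ± 0.41 (SE; adjusted p = 2.2e-06), with a median of 10.7 CPM in ABC and 0.562 CPM in GCB lines. The ABC lines RCK8 (−0.58 log2 CPM) and HLY1 (−0.72) lay near its GCB mean of −0.69. CD36, a scavenger receptor for fatty acids and lipoproteins (ENSG00000135218.18_4, GRCh37 chromosome 7, 79998891 to 80308593), was higher by 9.14 ± 1.08 (adjusted p = 1.7e-05), with medians of 8.11 and 0.065 CPM and all 9 ABC lines above the GCB median. Not all of them expressed CD36 clearly: RCK8 was at −2.80 log2 CPM, near the GCB mean of −3.00. U2932 (−0.19) lay below the GCB line FARAGE (0.92). INPP4B, a phosphoinositide phosphatase (ENSG00000109452.12_4, chromosome 4, 142944313 to 143768585), was higher by 8.01 ± 1.02 (adjusted p = 4.4e-05), with medians of 7.37 and 0.0207 CPM and a count in 11 of 20 GCB lines. With limma on log2 TPM plus 1 the changes were 2.42 for CD36 and 1.31 for INPP4B, both called, so the size of these 2 changes depended on the fit. GCB medians of both were near or under the floor, and CD36 averaged 122 CPM in ABC lines, far above its median there. The fitted change compares group means of CPM (122 and 0.214 for CD36, 22.5 and 0.0859 for INPP4B), so the highest lines weigh most in it. How far the low GCB levels added to its size was not tested. IL7, a lymphocyte growth factor (ENSG00000104432.13_3, chromosome 8, 79587978 to 79717758), was higher by 4.09 ± 0.51, at a median of 28.9 against 1.22 CPM. ZNF460 rose by 1.45 ± 0.19, a small change, with all 9 ABC lines above the GCB median.

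Among the other genes with the largest rises were CXCL10, an interferon-induced chemokine (7.47 ± 1.29), ENPP2, which encodes autotaxin (6.68 ± 1.03), the potassium-chloride cotransporter SLC12A7 (7.18 ± 1.09), RNF157 (6.66 ± 1.11) and BTBD16 (7.42 ± 1.17). MNDA, a nuclear antigen of myeloid and some B cells, rose by 9.09 ± 1.20 through 5 of 9 ABC lines, the only ABC lines above the GCB median. GCB medians of these 6 genes were 0.0122 to 0.11 CPM, near or under the floor. Some ABC lines were far above the others: CXCL10 averaged 129 CPM in ABC lines at a median of 2.55 CPM. Since fitted changes compare group means of CPM (129 and 0.718 for CXCL10), such lines weigh most in their size. What the low GCB levels added was not tested. Without the ABC line RCK8 the change of RNF157 was 3.80, and with limma on log2 TPM plus 1 it was 0.66 and not called (adjusted p = 0.154). With limma-voom, MNDA (adjusted p = 0.171) and BTBD16 (adjusted p = 0.125) were not called.

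Of the protein-coding genes lower in ABC lines, 13 are given here, the 5 with the smallest p and the 8 with the largest changes among those averaging at least 5 CPM in GCB lines. GNA13, a G protein subunit that restrains germinal centre B cells (ENSG00000120063.9_2, chromosome 17, 63006833 to 63052957), fell by 1.27 on the log2 scale (SE 0.23, adjusted p = 0.0012). Its mean log2 CPM was 8.56 ± 0.67 in GCB and 7.39 ± 0.26 in ABC lines (SD). STK17B, a kinase of the death-associated family, was at −1.65 ± 0.30, PXK at −2.10 ± 0.35, BCAS4 at −2.0 ± 0.33 and ZMYM1 at −2.10 ± 0.31, and for each of these 5 genes 0 of 9 ABC lines lay above the GCB median. The largest changes were those of INSR, the insulin receptor (−8.82 ± 2.03), the cytokine receptor IL7R (−8.71 ± 2.28), the RNA-binding protein gene LIN28B (−8.71 ± 2.49), the surrogate light chain gene IGLL1 (−8.45 ± 2.31), PTPRT (−8.35 ± 2.34), CCDC85A (−8.26 ± 1.91), ZNF239 (−7.98 ± 1.91) and PMEPA1 (−7.94 ± 1.58). Of 9 ABC lines, 4 lay above the GCB median for LIN28B, 2 for IL7R, 2 for IGLL1, 1 for PTPRT and 0 for the rest. Medians of LIN28B were 0.0320 CPM in ABC and 0.0521 CPM in GCB lines, so its change rested on a part of the GCB lines. GCB medians of these 8 genes were 0.0521 to 1.82 CPM, and with limma-voom none of the 8 was called (adjusted p from 0.29 to 0.657). With limma-voom their changes ran from −5.22 in INSR to −2.04 in PTPRT and with limma on log2 TPM plus 1, which called none of them, from −1.93 in IGLL1 to −0.72 in PTPRT. With the log10 total count as a covariate LIN28B was at −3.31 and PTPRT at −3.09, both uncalled. Calls of 3 of the 8 genes also ended without single lines: LIN28B without each ABC line but U2932 (adjusted p up to 0.0761, without LY3), IGLL1 without HBL1, OCI-LY10, HLY1, TMD8, SUDHL2 or LY3 (up to 0.0591), and PTPRT without BJAB or each ABC line but SUDHL2 (up to 0.0684).

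At an unadjusted p under 0.05 there were 4048 genes. The count of genes lower in ABC lines fell from 279 to 170 without LY3 and to 177 without TMD8. In the simulation, which had a simpler spread than the real lines, the test recovered 14% of 2-fold and 86% of 8-fold changes. Smaller differences can thus have gone uncalled.

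**Figure D2:**
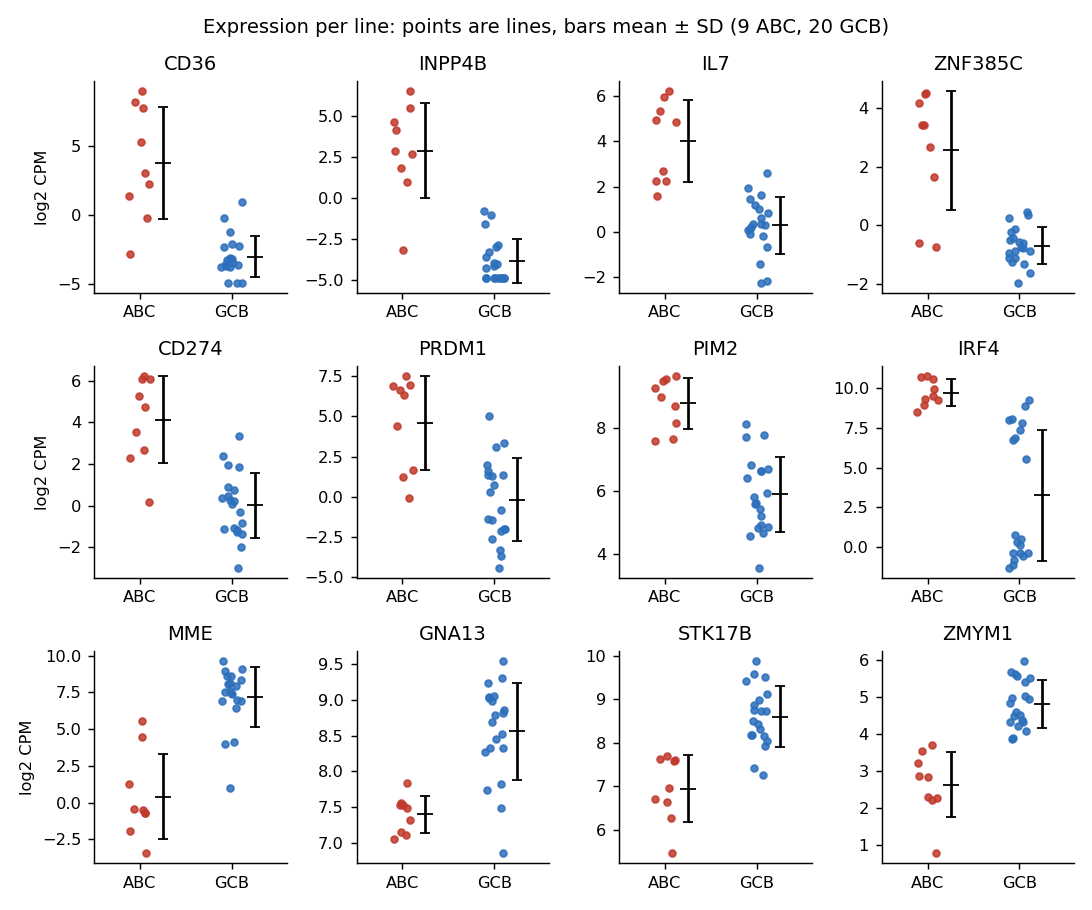
Log2 CPM of 12 named genes is plotted for each line, with ABC and GCB lines side by side, 1 point per line and bars for the mean and SD of 9 and 20 lines. PRDM1 and CD274 lie higher and MME lies lower in ABC lines. GCB lines fall into a lower and a higher cluster for IRF4, as ABC lines do for PRDM1.

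Of 24 ABC subtype genes, 11 rose and 0 fell (17 rose when adjusted over the list alone), with a median log2 fold change of 2.15. Among them were the survival kinase gene PIM2 (2.58 ± 0.40, adjusted p = 0.00025, 504 against 52.3 CPM at the median) and RAB29, a small GTPase gene (3.07 ± 0.47). Of 19 GCB subtype genes, 4 fell and 0 rose (12 fell when adjusted over the list alone), with a median of −1.54. They included MME, which encodes the germinal centre marker CD10 (−4.90 ± 1.06, adjusted p = 0.0062, 0.674 against 191 CPM), and the sphingosine phosphate receptor gene S1PR2 (−2.75 ± 0.67, adjusted p = 0.015; 0.0651 with limma-voom). Both lists were called by camera (adjusted p = 1.6e-18 and 5.4e-10, and adjusted p = 0.0217 and 0.0271 with an estimated correlation), and neither is independent evidence, since subtype labels rest on such genes.

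Of 27 tested targets of NF-kB, a transcription factor of B cell activation, 5 rose and 0 fell (12 adjusted over the list alone), with a median of 1.6. The apoptosis inhibitor CFLAR rose by 2.62 ± 0.44 (adjusted p = 0.00051) and NFKBIZ, a nuclear regulator of NF-kB, by 2.88 ± 0.61 (adjusted p = 0.0052), each in 9 of 9 ABC lines relative to the GCB median. CFLAR is also an ABC subtype gene. The NF-kB list was called (adjusted p = 7.4e-12) but had an adjusted p of 0.0622 with an estimated correlation. Of 21 cytokine and JAK-STAT genes, 6 rose and 0 fell (9 adjusted over the list alone), with a median of 1.21. STAT3, a transcription factor downstream of cytokine receptors, rose by 2.26 ± 0.40 (adjusted p = 0.0012), and PIM2 belongs to this list too; 4 of its genes (BATF, PIM1, PIM2 and STAT3) are also ABC subtype genes. The list was called (adjusted p = 5.4e-10, and adjusted p = 0.0271 with an estimated correlation).

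In ABC lines 4 of 16 plasma cell genes rose and 4 of 21 germinal centre genes fell. PRDM1, the regulator of plasma cell differentiation (ENSG00000057657.16_5, chromosome 6, 106534195 to 106557814), rose by 4.31 ± 0.93 (adjusted p = 0.0063). Its mean log2 CPM was −0.18 ± 2.58 in GCB and 4.61 ± 2.92 in ABC lines (SD). The ABC lines fell into 2 clusters: HBL1, RCK8 and RIVA at −0.05 to 1.65 log2 CPM and the other 6 at 4.42 to 7.50. The elongation factor gene ELL2, which acts in immunoglobulin mRNA processing, rose by 3.86 ± 0.75 (adjusted p = 0.0027), and SEC11C, a signal peptidase subunit, by 2.40 ± 0.41 (adjusted p = 0.00078). Without U2932, SEC11C changed by 1.08. CREB3L2 and IRF4 of the plasma cell list are also ABC subtype genes. Of 16 plasma cell genes 4 rose and 0 fell (6 rose and 1 fell adjusted over the list alone), with a median of 0.76 and an adjusted p of 0.00011, or an adjusted p of 0.0929 with an estimated correlation. Of 21 germinal centre genes 4 fell and 0 rose (6 adjusted over the list alone), among them GNA13 and MME, and 10 of the 21 are also GCB subtype genes. Their list had a median of −0.74, an adjusted p of 5.0e-05 and an adjusted p of 0.161 with an estimated correlation.

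Antigen presentation and B cell identity genes moved less clearly. All 13 MHC class II genes had negative fold changes, with a median of −1.42, yet 0 passed the threshold over all genes with edgeR (2 adjusted over the list alone), against 4 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom. HLA-DRB5 had the smallest p (−3.38 ± 1.02, adjusted p = 0.0556), and reads can be shared between HLA paralogs. The list was called by camera (adjusted p = 1.6e-05) but not with an estimated correlation (adjusted p = 0.282). Of 20 B cell identity genes SPIB rose (1.97 ± 0.55, adjusted p = 0.034) and SPI1 fell (−2.21 ± 0.45, adjusted p = 0.0037; 1 rose and 2 fell adjusted over the list alone), both genes of ETS transcription factors of B cells. The list had a median of −0.46 and an adjusted p of 0.015, with an adjusted p of 0.531 with an estimated correlation. SPIB is also an ABC subtype gene. It was not called without OCI-LY10 (adjusted p = 0.0946), TMD8 (0.0967) or LY3 (0.0756), nor with limma-voom (0.82, adjusted p = 0.624). The list call ended without HLY1 (adjusted p = 0.385) and without RCK8 (adjusted p = 0.084).

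Of 16 BCL2 family genes 2 rose and 0 fell (6 adjusted over the list alone), with a median of 1.17: PMAIP1 (2.45 ± 0.53, adjusted p = 0.0067) and BID (1.27 ± 0.31, adjusted p = 0.014), both of which encode proteins that promote apoptosis. The list was called (adjusted p = 0.0022, and adjusted p = 0.0271 with an estimated correlation). Of its genes BMF is also an ABC subtype gene and BCL2A1 also an NF-kB target. PMAIP1 was at 1.6 and not called without U2932 (adjusted p = 0.0624). Of 14 costimulation and checkpoint ligand genes 2 rose and 0 fell (4 rose and 1 fell adjusted over the list alone), with a median of 0.33. CD274, which encodes the T cell inhibitor PD-L1, rose by 4.24 ± 0.64 (adjusted p = 0.0002, 27 against 1.08 CPM at the median), and TNFSF4, which encodes the ligand of OX40, by 2.67 ± 0.69 (adjusted p = 0.023). TNFSF4 was not called without RCK8 (adjusted p = 0.0753) or SUDHL2 (0.0611), nor with limma-voom (2.45, adjusted p = 0.0550). With limma on log2 TPM it was at 0.90 with 1 added (adjusted p = 0.0583) and 1.81 with 0.1 added (adjusted p = 0.0611). The list had an adjusted p of 0.0304, an adjusted p of 0.310 with an estimated correlation, and lost its call without RCK8 (adjusted p = 0.0755), SUDHL2 (0.0746) or KARPAS 422 (0.0507).

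Of 22 ribosome biogenesis and MYC target genes, with a median of −0.17, only NCL, which encodes nucleolin, was called (1 fell, also adjusted over the list alone; −0.55 ± 0.15, adjusted p = 0.029), and not without U2932 (adjusted p = 0.0613), SUDHL2 (0.0625) or LY3 (0.0698). The list had an adjusted p of 0.0026, or an adjusted p of 0.542 with an estimated correlation, and 0.0746 without SUDHL2.

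The number of lists called was not beyond that of random groupings. The labels gave 11 called lists of 24, while 5 of 100 splits of the lines into 9 and 20, the labels included, gave as many, and the highest other split gave 12. List by list, in a count chosen after seeing the data, 1 of 100 splits gave a camera p as small for ABC subtype, GCB subtype, cytokine and BCL2 family genes, and 2 did for NF-kB targets and for plasma cell genes. There were 5 such splits for germinal centre, 9 for costimulation, 13 for MHC class II, 23 for B cell identity and 29 for ribosome biogenesis genes.

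**Figure D3:**
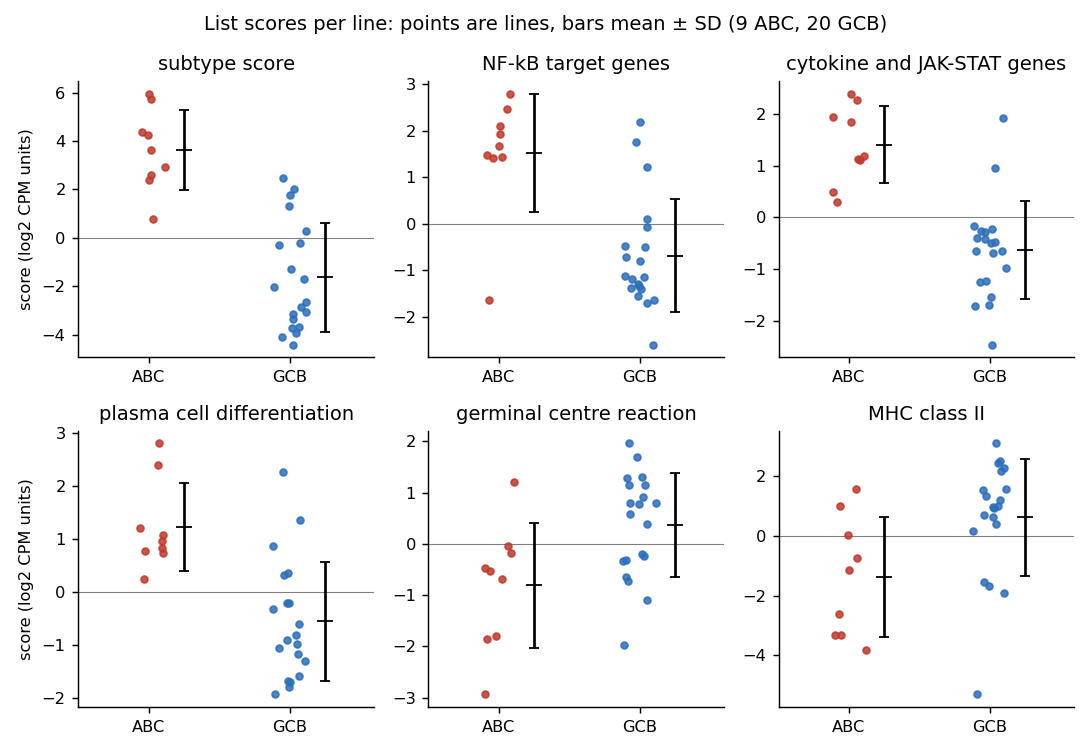
Scores of 6 panels, the subtype score and 5 gene lists, are plotted in log2 CPM units for each line, with ABC and GCB lines side by side and bars for the mean and SD of 9 and 20 lines. The ABC line far below the other ABC lines for NF-kB targets, at −1.63, is HLY1.

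The other 13 lists tested were not called. B cell receptor signalling had 0 of 23 genes called and a median of −0.30 (adjusted p = 0.150), with the smallest p in BCL10 (0.55 ± 0.17, adjusted p = 0.069). Of 14 Toll-like receptor and MYD88 genes, IRF5 rose (1.74 ± 0.47, adjusted p = 0.032) and MAP3K7 fell (−0.74 ± 0.18, adjusted p = 0.012), with the same counts adjusted over the list alone, a median of −0.07 and an adjusted p of 0.518. IRF5 was not called without OCI-LY10 (0.0549), TMD8 (0.0507), SUDHL2 (0.0644) or LY3 (0.0555), each an adjusted p. MHC class I had 0 of 14 called and a median of 0.08 (adjusted p = 0.961; TAPBP 0.36 ± 0.16). Interferon-stimulated genes had 0 of 24 called, with a median of −0.04 and a mean of −0.15 though camera's direction was up (adjusted p = 0.145), and RSAD2 at −4.30 ± 1.59 (adjusted p = 0.12). RSAD2 was at −2.02 without SUDHL16, and at −6.16 and called without HBL1 (adjusted p = 0.0479). In the PI3K-AKT list INPP4B rose and 17 of 18 genes were not called, with a median of −0.09, a mean of 0.22 and camera's direction down (adjusted p = 0.712).

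Cell cycle genes had 0 of 22 called (median −0.08, adjusted p = 0.483; MCM6 −0.76 ± 0.23) and oxidative phosphorylation genes 0 of 22 (median 0.09, adjusted p = 0.824; UQCRFS1 0.43 ± 0.14). Of 19 glycolysis genes only PKM, which encodes pyruvate kinase, rose (0.67 ± 0.19, adjusted p = 0.035), and not without U2932 (0.0797), HLY1 (0.0851) or SUDHL2 (0.0773), each an adjusted p; the list had a median of −0.02 (adjusted p = 0.615). Of 18 unfolded protein response genes HSP90B1, a chaperone gene, rose by 1.29 ± 0.30 (adjusted p = 0.011, and 0.078 without HLY1, RCK8 and PFEIFFER; 6 genes rose adjusted over the list alone), with a list median of 0.21 (adjusted p = 0.146). Of 14 chromatin modifier genes TET2, which encodes a DNA demethylase, rose by 1.84 ± 0.50 (adjusted p = 0.031), and not without TMD8 (0.0735) or LY3 (0.0560); the list had a median of −0.08 (adjusted p = 0.368). Replication-dependent histone genes had 0 of 17 called (median −0.08, adjusted p = 0.615; HIST1H2BD −0.36 ± 0.24). Adjusted over the list alone, the counts of these uncalled lists were the same where no other count is given. The lists with 0 calls by edgeR had more at an unadjusted p under 0.05: 4 B cell receptor, 3 MHC class I, 2 interferon, 4 cell cycle, 2 oxidative phosphorylation and 0 histone genes. DESeq2 called 1 gene each in the B cell receptor, interferon, cell cycle and oxidative phosphorylation lists and 0 in the MHC class I and histone lists, and limma-voom called 1 each in the B cell receptor and cell cycle lists and 0 in the others.

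Markers of other cell types were mostly uncalled, though single lines expressed some of them, such as KRT8 at 9.03 log2 CPM in SUDHL16 and 5.65 in OCI-LY10 and THY1 at 5.88 in SUDHL4. Of 8 T and NK cell markers tested, CD5, which some B cells also express, rose by 5.45 ± 0.83 (adjusted p = 0.00022) at medians of 0.207 and 0.085 CPM, and was not called with limma-voom (adjusted p = 0.103); the list was not called (median −1.01, adjusted p = 0.871; 1 rose and 1 fell adjusted over the list alone). The 5 stromal markers had 0 calls (2 fell adjusted over the list alone), a median of 0.75, a mean of −1.55 and camera's direction up (adjusted p = 0.249), with THY1 at −5.54 ± 1.85. Myeloid (4 tested), epithelial (1) and erythroid (1) markers were too few for a set test and had 0 calls (2 myeloid markers rose and 1 fell adjusted over the list alone): ITGAM was at 3.35 ± 1.04 (adjusted p = 0.062), ALAS2 at 0.46 ± 0.50, and KRT8 at −1.98 ± 1.8 (adjusted p = 0.59). At an unadjusted p under 0.05 there were 3 myeloid, 2 stromal, 0 epithelial and 0 erythroid markers; DESeq2 called 2 myeloid and 1 stromal marker, and limma-voom 0 and 1. ITGAM was at 0.74 without LY3, and at 3.93 and called without OCI-LY8 (adjusted p = 0.0266). Without SUDHL16 the change of KRT8 was 4.15 (adjusted p = 0.0106), so its direction rested on that line.

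Several genes central to lymphoma did not differ by the test. IRF4, a regulator of activated B and plasma cells (ENSG00000137265.14_2, chromosome 6, 391739 to 411447), had a fold change of 3.10 ± 1.03 (adjusted p = 0.084) although all 9 ABC lines lay above the GCB median. Of the GCB lines, 11 lay between −1.31 and 0.74 log2 CPM and 9 between 5.56 and 9.28, against 9.72 ± 0.82 (SD) in ABC lines. Other tests called IRF4: DESeq2 (3.11, adjusted p = 0.0204), limma-voom (6.39, adjusted p = 0.00041), and limma on log2 TPM plus 1 (5.09, adjusted p = 0.00205) or 0.1 (6.14, adjusted p = 0.00382). The germinal centre repressor BCL6 was at −1.43 ± 0.60 (adjusted p = 0.18), the apoptosis inhibitor BCL2 at 1.16 ± 0.76 (adjusted p = 0.43), the growth regulator MYC at −0.54 ± 0.31 (adjusted p = 0.35), the transcription factor FOXP1 at 1.36 ± 0.51 (adjusted p = 0.13) and the chemokine receptor CXCR4 at −0.49 ± 0.93 (adjusted p = 0.82). BCL2 was at 0.52 without RIVA, and CXCR4 at −1.38 without OCI-LY10.

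Of 2879 long noncoding genes tested, 128 were called, 86 higher and 42 lower in ABC lines. AC083837.2 (ENSG00000285744.1_1, chromosome 8, 79717528 to 79868317) rose by 8.13 ± 0.95 (adjusted p = 1.7e-05), with medians of 0.0291 CPM in GCB and 20.4 CPM in ABC lines. It overlaps IL7, on the other strand, by 231 bp and AC083837.1, on the same strand, by 2994 bp. AC025048.4, which overlaps the pseudogene WFDC21P on the other strand by 5130 bp, rose by 5.64 ± 0.74, and AC005261.5, which overlaps ZNF460 on the other strand by 487 bp, by 1.41 ± 0.20. Lower in ABC lines were AC008555.1 (−5.44 ± 0.84), LINC01400 (−3.57 ± 0.65) and AC079209.1 (−4.63 ± 0.95). AC008555.1 had a count in only 2 of 9 ABC lines and all 20 GCB lines. It overlaps LINC01801 on the same strand by 21281 bp and AC008555.2 on the other by 3326 bp. By the deposited positions, LINC01400 lies wholly within the entry of SNORA31 on the same strand (2262 bp). AC008555.1 and LINC01400 were near the floor, with medians of 0 CPM in ABC and 0.326 and 0.156 CPM in GCB lines. Their changes were as small as −0.28 and −0.43 in alternative runs. With limma-voom AC079209.1 was at −4.35 and not called (adjusted p = 0.062). The strand setting of the authors' counting was not stated, so reads of overlapping genes on opposite strands can have been counted for either, and the labels do not say how reads of genes overlapping on 1 strand were assigned. By class, 678 protein-coding genes were called (485 higher, 193 lower), as were 89 pseudogenes and 18 immunoglobulin or T cell receptor segments (7 higher, 11 lower).

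Called genes were unevenly spread along chromosomes, in a view chosen after seeing the data. On chromosome 19 from 40000001 to 60000000, 54 of 251 protein-coding genes above 2 log2 CPM were higher and 1 lower in ABC lines, or 21.9% called against 3.90% over all such windows. On chromosome 18 from 40000001 to 60000000, 12 of 38 were higher and 0 lower. On chromosome 6 from 100000001 to 120000000, 10 of 51 were lower and 1 higher, and on chromosome 1 from 20000001 to 40000000, 9 of 150 were lower and 2 higher. These windows were chosen by their number of calls. By share called, windows not described ranked above that of chromosome 1 (7.33%), such as chromosome 3 from 100000001 (16.3%) and chromosome 10 from 120000001 (15.6%). PMAIP1 and SEC11C lie in the chromosome 18 window and ZNF460 and SPIB in the chromosome 19 window.

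**Figure D4:**
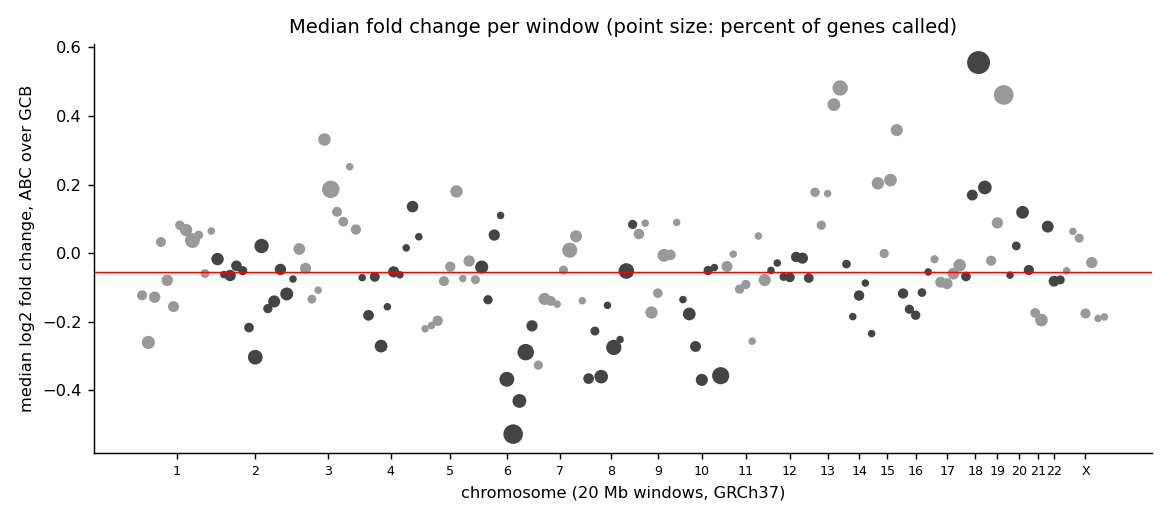
Each point is a 20 Mb window of the genome, placed by chromosome, with the median log2 fold change of ABC over GCB lines of its protein-coding genes on the y axis, the percent of genes called as point size, and the median of all genes (−0.06) as a line. The windows on chromosomes 18 and 19 with 31.6% and 21.9% of genes called lie at 0.56 and 0.46, with 1 window of chromosome 13 between them at 0.48, and the chromosome 6 window lies lowest, at −0.53.

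Loss of expression was scored where a gene lay under 1 in 20 of its median over all lines. MME was lost in 7 of 9 ABC lines and 1 of 20 GCB lines, NU-DHL1 (Fisher's exact test, adjusted p = 0.00323), and no other gene reported here differed by this test. MME is a GCB subtype gene, of the kind on which such labels rest, so its loss is not independent evidence of the grouping. The cell cycle inhibitor genes CDKN2A and CDKN2B, neighbours on chromosome 9, were both lost in DB, DOHH2, OCI-LY10, NU-DHL1, TMD8 and LY3. MTAP, a neighbouring gene of methionine salvage, was lost in DOHH2, RCK8, NU-DHL1, HLY1, TMD8 and LY3, thus in 4 of 9 ABC and 2 of 20 GCB lines (Fisher's exact test, adjusted p = 0.531). BCL2 was lost in 5 GCB lines (BJAB, HT, OCI-LY7, SUDHL10 and SUDHL5) and CXCR4 in DB, HT, KARPAS 422, SUDHL16 and the ABC line HBL1. PRDM1 was lost in OCI-LY1, SUDHL10 and SUDHL4, and TNFRSF14, a ligand of a T cell inhibitory receptor, in KARPAS 422, OCI-LY18 and SUDHL6. CD58, which T cells bind, was lost in HBL1, LY3, OCI-LY7 and SUDHL4, and S1PR2 in HBL1, OCI-LY10 and TOLEDO. These counts moved with the limit: PRDM1 was lost in 7 GCB lines at 1 in 10 and in 2 at 1 in 50 of the median. S1PR2 was lost in 4 lines at 1 in 10 and in 0 at 1 in 50. At 1 in 50, BCL2 was lost in 4 GCB lines, and CXCR4 in 3 GCB lines and 0 ABC lines. A gene scored as lost could still be expressed: BCL2 was at 3.72 log2 CPM in SUDHL5, and CXCR4 at 1.92 in HBL1 and 2.04 in HT. Fold changes of these genes were not called for CDKN2A (−0.15 ± 0.88), CDKN2B (1.31 ± 0.89), MTAP (−1.21 ± 0.86), CD58 (0.46 ± 0.94) and TNFRSF14 (−0.02 ± 0.77). That of TNFRSF14 turned to 0.028 when scaled by library size. Single lines moved others: CDKN2B was at 0.38 without U2932, and CD58 at 1.51 without FARAGE and 0.14 without HLY1. RB1, B2M, CIITA, GNA13, CREBBP, KMT2D, NFKBIA, NFKBIE, TMEM30A and MYC were lost in 0 lines. RNA levels cannot tell a deleted gene from a silent one.

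**Figure D5:**
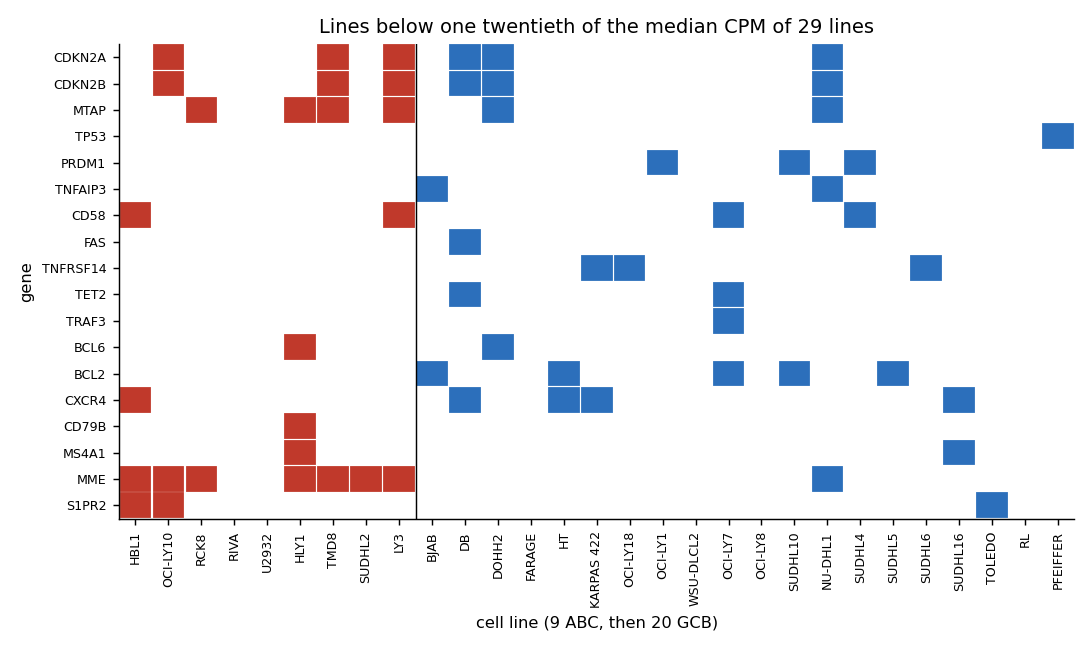
Genes lost in at least 1 line, of those reported here, are listed down the side and the 9 ABC and then the 20 GCB lines along the bottom, and a filled cell marks a line below 1 in 20 of the gene's median CPM over the 29 lines (red for ABC, blue for GCB). MME is lost in 7 of 9 ABC lines and in 1 of 20 GCB lines.

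Pairs of regulators were related within groups in 3 of 14 tests. In the 20 GCB lines CIITA, the activator of MHC class II genes, followed the MHC class II score (r = 0.66, permutation p = 0.00514, adjusted p = 0.036; rho = 0.49, permutation p = 0.0321, adjusted p = 0.0933), and BCL6 ran against PRDM1, which it represses (r = −0.57, permutation p = 0.00876, adjusted p = 0.0409; rho = −0.44, permutation p = 0.0537, adjusted p = 0.125). The first relation rested on DB and OCI-LY1 (r = 0.29 without them) and the second on DOHH2 and NU-DHL1 (r = −0.26 without them). In the 11 GCB lines with little IRF4, IRF4 followed the NF-kB target score (r = 0.85, permutation p = 0.00066, adjusted p = 0.00924; rho = 0.80, permutation p = 0.00478, adjusted p = 0.0669). Without RL and KARPAS 422, r was 0.70 with a permutation adjusted p of 0.202. Lines in 2 clusters of IRF4, PRDM1 or BCL2 were tested within clusters of at least 6 lines, a rule chosen after seeing the data.

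The other 11 relations did not pass. In the 9 ABC lines r was 0.74 for CIITA and MHC class II (exact adjusted p = 0.0804), 0.43 for MYC and ribosome biogenesis (exact adjusted p = 0.345), −0.43 for MYC and BCL2 (exact adjusted p = 0.345) and −0.38 for IRF4 and NF-kB targets (exact adjusted p = 0.411), which turned to 0.51 without HLY1 and TMD8. In the 6 ABC lines with higher PRDM1, r was −0.74 for BCL6 and PRDM1 (exact adjusted p = 0.0778) and 0.55 for IRF4 and PRDM1 (exact adjusted p = 0.395). Among GCB lines r was 0.35 for MYC and ribosome biogenesis, −0.23 and 0.42 for IRF4 and PRDM1 in lines with lower and higher IRF4, 0.49 for IRF4 and NF-kB targets with higher IRF4, and 0.30 for MYC and BCL2 with higher BCL2 (permutation adjusted p from 0.326 to 0.512).

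Some genes were expressed in a single line. Under the rule of at least 20 CPM and 50-fold above the next line, 75 protein-coding genes were restricted to 1 of 17 lines, and HLY1 held 27 of them. They included RELN, which encodes the extracellular matrix protein reelin (359 CPM in HLY1, 0.290 in the next line), and the chemokine receptor CCR2 (255 CPM in HLY1). SUDHL16 held 8, among them ALDH1A1 (911 CPM), a retinal dehydrogenase gene, and RCK8 and PFEIFFER held 7 each. T cell genes appeared in this form: CD8A at 588 CPM in PFEIFFER and CD3G at 190 CPM in KARPAS 422. The B cell attracting chemokine CXCL13 was at 642 CPM in LY3, and EPHA7 at 592 CPM in BJAB. These examples were chosen after their values were seen, and no test applies to single lines.

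Of 7 measures of RNA composition 1 passed the test. A count was found for 28726 ± 1072 genes in ABC and 26970 ± 1121 genes in GCB lines (SD; exact permutation adjusted p = 0.0081), and at an equal depth of 34.3 M counts for 27562 ± 1201 and 26014 ± 1269 genes (exact permutation adjusted p = 0.049). Mitochondrial genes held 0.580 ± 0.118% and 0.485 ± 0.0758% of counts (exact permutation adjusted p = 0.0603), and without OCI-LY10, which was grown in human plasma, the difference of 0.119 points passed the test (exact permutation adjusted p = 0.0116). Histone genes (0.683% and 0.737%), 7SL and 7SK RNA (6.35% and 6.11%), immunoglobulin genes (0.580% and 0.363%) and the 10 largest genes (11.4% and 10.6%) did not differ (exact permutation adjusted p from 0.323 to 0.692). The ratio of chi-square to degrees of freedom between counts was 249 for the closest pair, WSU-DLCL2 and SUDHL10 (r = 0.939), and 764 for OCI-LY1 and HLY1 (r = 0.832), a pair compared since the title of HLY1 was corrected by the submitters.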

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

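The tests of a wrong label for RCK8, HLY1 and PFEIFFER were chosen only after the closest lines had been seen. Among 108 values tested within the 9 ABC lines, 7 held 1 line far from the others, measured by its gap to the nearest line relative to the whole range, and chance gives 5.4. HLY1 had 3.0 log2 CPM of BCL6, where the other ABC lines had 5.42 to 7.72, and −3.53 log2 CPM of SPI1, where they had 0.17 to 3.21. Its score of NF-kB target genes was −1.63, against 1.41 to 2.80 in the other ABC lines. U2932 had 11.53 log2 CPM of SEC11C, against 6.61 to 8.30. RCK8 had −4.92 log2 CPM of AC083837.2, where the other ABC lines had 1.01 to 5.87. RIVA had 1.5 log2 CPM of TNFRSF14, against 2.97 to 3.50. OCI-LY10, the line grown with human plasma, had a MHC class I score of −2.68, against −0.43 to 1.51.

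The ABC lines RCK8 and HLY1 and the GCB line PFEIFFER lay closest to a line of the other group. A wrong label was tested with the subtype score, which should then lie inside the range of the other group. The score of HLY1 was 3.64, above every GCB line (highest 2.46), and so was its score on 15 genes (4.06, highest GCB line 3.34). RCK8 at 2.39 and PFEIFFER at 1.33 lay within the ranges of both groups, while on 15 genes RCK8 (4.25) lay above every GCB line and PFEIFFER (1.14) below every ABC line (lowest 1.87). The subtype score of PFEIFFER was nearer the ABC mean (3.63) than the GCB mean (−1.63) and above that of the ABC line U2932 (0.79), and on the first principal component PFEIFFER had the highest value of the GCB lines (41.1), above the ABC lines U2932 (30.1), RCK8 (33.3), HLY1 (35.7) and RIVA (38.3). Where a score of 1 of the 3 lines lay outside the range of the other group, the gap was smaller than the SD of that group, so a wrong label is not excluded for any of the 3. The biological alternative, that lines of 1 group differ this much from each other, stays open for all 3 lines; without them 1105 genes were called, 695 of them shared with the 929.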

How the results depend on the processing

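Results with the log10 total count, with legacy=FALSE, and without HLY1 alone or with RCK8 and PFEIFFER were chosen only after the results were seen. Of 53 called named genes, 31 kept direction and call in every alternative run that tested them (at most 42 each). Runs that did not test a gene were not counted for it, and LIN28B was tested in 21 of the 29 runs that left out a line. The other 22 called genes lost the call in at least 1 run and 0 changed direction. Of 22 uncalled ones, 8 were called in at least 1 run with the direction kept, and 5 changed direction. One of those 5, KRT8, was called in the opposite direction without SUDHL16. The cause was not tested except where fewer genes or lines were used. The 929 called genes became 4171 (3454 higher, 717 lower; 1176 long noncoding) with no filter, which tests more genes, 604 (401 higher; 65 long noncoding) at 1 CPM in 9 lines, 1634 (722 lower; 223 long noncoding) with DESeq2, 377 (293 higher, 84 lower; 61 long noncoding) against 1.5-fold and 1617 (1089 higher, 528 lower; 270 long noncoding) with legacy=FALSE; of the 929, 580 were shared at 1 CPM, 847 with DESeq2, 531 with limma-voom (1020 called) and 460 and 509 with limma on log2 TPM plus 1 (755 called) and 0.1 (862 called). Leaving out each line gave 666 to 1098 genes, 496 to 763 higher, 170 to 335 lower and 91 to 152 long noncoding.

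Adjusted p of lists is given here. With an estimated correlation 4 lists were called, and NF-kB targets (0.0622), plasma cell (0.0929), B cell identity (0.531), germinal centre (0.161), MHC class II (0.282), ribosome biogenesis (0.542) and costimulation genes (0.310) were not. With fry, B cell identity (0.205) and ribosome biogenesis (0.198) were not called, and MHC class I (0.859) turned direction. With library number, B cell identity (0.0604) and ribosome biogenesis (0.0871) lost the call, interferon (0.0278) and unfolded protein response genes (0.0298) gained it, and MHC class I (0.886) turned. Interferon genes were called at 1 CPM (0.0389). Without OCI-LY10 oxidative phosphorylation (0.852) turned, and with log10 total count MHC class I (0.970) did. Without HLY1, RCK8 and PFEIFFER, B cell identity (0.819) lost the call, and B cell receptor (0.422), Toll-like receptor (0.820), MHC class I (0.534), oxidative phosphorylation (0.422) and T and NK cell lists (0.711) turned. Without HLY1, B cell identity (0.385) lost the call, and MHC class I (0.665) and oxidative phosphorylation (0.897) turned. Leaving out each line gave ranges of 0.0035 to 0.385 for B cell identity, 0.0372 to 0.940 for B cell receptor, 0.404 to 0.990 for MHC class I, 0.686 to 0.962 for T and NK cell, 0.0073 to 0.0755 for costimulation, 0.0226 to 0.684 for interferon, 0.0896 to 0.981 for oxidative phosphorylation, 0.326 to 0.962 for histone, 3.9e-05 to 0.0746 for ribosome biogenesis and 0.0157 to 0.442 for unfolded protein response genes.

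Among uncalled genes, TNFRSF14 turned to 0.028 (library size), 0.0059 (1 CPM), 1.66 (voom), 0.45 and 1.13 (TPM plus 1 and 0.1) and 0.36 (library number); KRT8 to 1.67 (DESeq2), 2.44 (voom), 0.25 and 1.16 (TPM plus 1 and 0.1), 2.81 (library number) and 1.51 (log10 total count); CXCR4 to 0.12 (voom) and 0.044 (TPM plus 0.1); CDKN2B to −0.91 (voom) and −0.13 (TPM plus 0.1); and CDKN2A to 0.022 (without OCI-LY10). Leaving out each line gave −0.61 to 0.037 for CDKN2A, −4.34 to 4.15 for KRT8, −0.091 to 0.42 for TNFRSF14, 0.74 to 3.93 for ITGAM, −6.16 to −2.02 for RSAD2, 0.38 to 1.48 for CDKN2B, 0.14 to 1.51 for CD58 and −1.38 to −0.24 for CXCR4. At 20-fold there were 147 line-restricted genes. Without OCI-LY10 the mitochondrial difference of 0.119 points passed the test (exact permutation adjusted p = 0.0116). With TPM, r was 0.86 for CIITA and MHC class II in ABC lines, −0.76 for BCL6 and PRDM1 in ABC lines with higher PRDM1 (both newly called) and −0.59 in GCB lines (no longer called). Without the 2 lines farthest from the median, r was 0.51 (IRF4 and NF-kB targets, ABC lines, turned), 0.29 (CIITA and MHC class II, GCB lines), −0.26 (BCL6 and PRDM1, GCB lines) and 0.70 (IRF4 and NF-kB targets, GCB lines with lower IRF4), the last 3 no longer called. Depth limits genes under 0.0347 to 0.0874 CPM, where no difference was detectable. The subtype score difference and the loss of MME kept direction and call in every alternative run. Neither is independent evidence of the grouping, since subtype labels rest on such genes.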

Other observations

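The count of splits for long noncoding genes was chosen only after its result was seen, as were the number of windows weighed and their limits on level and gene number. The highest immunoglobulin heavy chain constant gene differed between lines. IGHM, the heavy chain of IgM, was the highest heavy chain constant gene in 5 of 9 ABC and 11 of 20 GCB lines, IGHG3 in 3 ABC lines and 1 GCB line, IGHA1 in 1 ABC line, IGHG4 in 5 GCB lines and IGHG1 in 3 GCB lines. The highest gene held up to 99.5% of heavy chain constant CPM (OCI-LY7), but 39.5% in RCK8, 39.6% in LY3 and 52.5% in PFEIFFER. In these lines the class was thus not clear. Constant genes are paralogs that share reads, and no test was run. HLY1 combined the lowest ABC scores of B cell receptor signalling (−4.14) and B cell identity (−4.23) with the highest plasma cell score of all ABC lines (2.81), and had lost CD79B and MS4A1, which encode B cell surface proteins. SUDHL16, a GCB line, had also lost MS4A1 and had the lowest GCB score of B cell identity (−1.46).

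Random groupings of the lines were compared with the labels. Of 100 splits into 9 and 20 lines, the labels included, 1 gave as many called genes as the labels' 929. The highest other split gave 56, so the count lay beyond those of the other splits drawn. Since subtype labels rest on gene expression, this shows that the labels follow expression. It cannot exclude chance for single calls. For the 128 long noncoding genes 1 of 100 splits gave as many, with 7 as the highest other. For gene lists chance cannot be excluded, since 5 of 100 splits gave at least the 11 lists called with the labels and the highest other gave 12.

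More genes were called higher than lower in ABC lines (70.0% of 929). Scaling as the whole cause is argued against: the percent moved by at most 2.304 points under the other scalings, to 72.3% with library size. The unequal group sizes may account for the excess, because in 43 other splits with at least 10 calls a median of 100% of calls were higher in the group of 9, and the lowest was 91.7%. The share under the labels lies below those of the random splits, and with DESeq2 it was 55.8%. A biological excess stays open and untested.

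Called genes clustered on chromosomes, as described for chromosomes 1, 6, 18 and 19. A candidate explanation is chromosomal dosage, gains or losses of segments at different frequency in the groups, under which uncalled genes of a window should shift with the called ones. The median fold change of uncalled genes, minus that of all uncalled genes, was 0.388 for chromosome 19 from 40000001, 0.485 for chromosome 18, −0.433 for chromosome 6 and −0.183 for chromosome 1. In windows with 0 called genes this shift ran from −0.199 (chromosome 11 from 80000001) to 0.310 (chromosome 3 from 160000001). The chromosome 1 shift lay inside that range, so it cannot decide on dosage there. Shifts of the windows on chromosomes 6 and 18 and on chromosome 19 from 40000001 lay outside it, as dosage predicts. These windows were chosen by calls in the same lines. Genes of all 4 windows also correlated across lines above the 95th percentile of random sets (mean r of 0.205, 0.430, 0.190 and 0.192 against 0.0255, 0.0506, 0.0380 and 0.0282). The shift was 0.035 on chromosome 19 from 1, the window next in number of calls, though only 2.88% of its genes were called. Genes there also correlated across lines (mean r = 0.224, 95th percentile of random sets 0.024), so correlation alone is not specific and dosage stays undecided there. Reads shared among zinc finger paralogs are argued against as the whole cause on chromosome 19, since the 165 genes without ZNF in their name were shifted by 0.460; copy number was not measured.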
